A study of Caenorhabditis elegans with 4 samples.

How the data were processed

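Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on mixed-stage embryos of the wild-type Caenorhabditis elegans strain N2, grown at 20 °C and fixed with 1% formaldehyde for 5 min. The antibody was an affinity-purified rabbit polyclonal against HCP-4, used at 5 µg per reaction on 3 mg of protein extract, per the labels' protocols. The 4 samples comprise 2 ChIP libraries and 2 input DNA libraries, and each was assigned to its group and replicate number from its title. Peak lists of the 2 ChIP libraries and 1 list for the whole series were analysed; the input libraries were not analysed here.

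Reads were aligned with BWA to ce10, per the submitters' processing notes. The file headers give the genome build as WormBase WS220, the WormBase name for that build. Peaks were called with MACS for each ChIP library and with MACS version 2 for the series-level list, per the source column of each file. The BWA version, the MACS version of the replicate lists, the calling threshold, the use of the inputs and the way the libraries were combined for the series-level list are not given in the sources used here. Each deposited peak carries a start, an end and 1 score, which is the peak caller's own value. The scale of the score was not stated in the files, and the deposited scores of the series-level list (1.35 to 66.1) and of the replicate lists (50.1 to 3123) lie on different scales. Scores were therefore used to describe, rank or filter peaks within a list, and to correlate overlapping peaks of the replicate lists by rank. In 1 alternative the log10 scores themselves were correlated between the replicate lists (Pearson), which assumes that these lists share a scale. Exactly 3100 was listed for 21 peaks of replicate 1 and 17 peaks of replicate 2, so the highest replicate scores are largely tied. Read counts and sequencing depth of the libraries are unknown, and no value given here has an interval that needs them. Intervals on shares of peaks are 95% Wilson intervals, or exact binomial intervals for the X chromosome, and cover the number of peaks only. Peaks are not replicates, so p-values over peaks describe where the peaks of a list lie and not the variation between embryo preparations. Nothing in the labels says whether the libraries came from separate cultures.

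Peak lists were compared with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Peaks were called shared when they overlapped by at least 1 bp. Overlap between replicates was tested against 10000 random placements of one list within each chromosome, keeping peak widths, one-sided, and the smallest p this can give is 0.0001. Such a test, which redraws peak positions, is called a placement permutation test. Each chromosome was divided into 3 parts of equal length, and the left and right parts are called the outer parts. The share of peaks in the outer parts and the median gap between neighbouring peaks were tested with placement permutation tests, two-sided, and the smallest p is 0.0002. The number of peaks on X was tested against chromosome extent with an exact binomial test, and the 6 chromosomes together by a chi-square statistic against 100000 multinomial draws. Medians and rank correlations were tested with 100000 permutations, two-sided, and the smallest p is 1e-05. Shares of peaks per chromosome or region were compared between replicates with Fisher's exact test, two-sided. Benjamini-Hochberg adjustment was applied within each family, which is named beside the value. The extent of each chromosome was taken from base 1 to the largest peak end in the 3 lists, which falls short of the chromosome end where no peak lies near it. Nominal WS220 lengths, entered from general knowledge of the build and not from the files, were used as an alternative. Mitochondrial peaks were left out of all tests on nuclear chromosomes. The placement tests were tested on simulated data: in 100 pairs of unrelated lists with the sizes of the replicates, p was under 0.05 in 6 for overlap, and for 100 simulated replicate 1 lists in 3 for outer parts and 5 for gaps. With 200 planted shared peaks a median of 202 overlapping peaks was found, and p was under 0.05 in 100 of 100 simulations. The simulated peaks were placed independently, as the tests themselves place them. These rates therefore do not extend to lists whose peaks are bunched.

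The tests of replicate overlap, X against autosomes, outer parts, gaps and rank agreement, most alternatives and the rule for named regions were fixed before the data were examined. The comparisons by score class, of shared with unshared peaks, of widths on X, of chromosomes between replicates and of dense regions were added after seeing the data. The dense regions were the 10 with the most series-level peaks, so they were picked for their density. The rule names the 25 highest-scoring series-level peaks that overlap both replicate lists, the 5 highest-scoring unshared peaks of each replicate, and the widest and narrowest series-level peak. Alternatives were a stricter overlap, the upper 50% or 25% of a list by score, other random placements, another division of chromosomes, and bases in place of peaks. Each single replicate list was also used in place of the series-level list, which itself was not remade without a replicate. Joining peaks less than 10 kb apart into regions, nominal lengths, rotation of the list for the outer parts, and leaving out dense regions were added after seeing the data. The 4 planned results that need gene annotation or sequence of WS220 (distance to gene starts, annotated feature, gene lists and base composition) were not computed, because the annotation at hand was for the assembly WBcel235 and coordinates were not moved between builds. No gene is therefore named at a peak, and no exon, intron or UTR is given.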

Results

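HCP-4 is the C. elegans counterpart of CENP-C, an inner kinetochore protein. The chromosomes of this nematode are holocentric, meaning that the kinetochore forms along their length and not at a single centromere. ChIP-seq with an HCP-4 antibody in N2 mixed embryos addressed where on the genome the protein is found. The peak lists of 2 ChIP replicates and a series-level list were examined. Coordinates are 1-based on WS220.

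Called HCP-4 peaks were few, mostly short, and covered under 1% of the nuclear genome. The calling threshold and the use of the inputs are not given, so this share does not measure how much of the genome HCP-4 occupies. Replicate 1 had 569 peaks and replicate 2 had 448, a mean of 508.5 ± 85.6 (SD, n = 2), and the series-level list had 672. Nuclear peaks covered 426 kb in replicate 1 and 347 kb in replicate 2, or 386 ± 55.9 kb (SD, n = 2), and 508 kb in the series-level list, which is 0.510% of the 99.7 Mb spanned. The median peak was 307 bp wide in replicate 1, 347 bp in replicate 2 and 362 bp in the series-level list. A minority of wide peaks held much of the covered sequence. In the series-level list, 56 nuclear peaks were at least 2 kb wide and held 41.8% of the covered bases; the corresponding share was 49.7% in replicate 1 (56 peaks) and 43.7% in replicate 2 (43 peaks).

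The first comparison asked which sites recurred between the replicates. Of 447 nuclear peaks in replicate 2, 353 overlapped a replicate 1 peak (79.0%, 95% Wilson interval 75.0 to 82.5%). Of 568 in replicate 1, 321 overlapped a replicate 2 peak (56.5%, interval 52.4 to 60.5%). Random placement gave a mean of 3.26 and 3.13 overlapping peaks, and no placement reached the observed number (placement permutation test, one-sided p = 0.0001 for each, the smallest possible). The test addresses independent placement only. Input coverage was not analysed, so recurrence does not tell HCP-4 binding from other signal common to both libraries. By sequence, 314 kb lay under peaks in both replicates, 73.7% of the replicate 1 and 90.5% of the replicate 2 bases.

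Recurrence rose with peak score. Each list was divided by score into 4 classes of nearly equal size. In the highest class, 97.2% of replicate 1 peaks (138 of 142) and 98.2% of replicate 2 peaks (110 of 112) were found in the other replicate. In the lowest class these shares were 22.5% (32 of 142) and 48.2% (54 of 112). Shared peaks had a median score of 243 in replicate 1 against 69.1 for unshared peaks, and were wider, at 517 against 204 bp. In replicate 2 the medians were 228 against 64.9 and 484 against 171.5 bp. Each of these 4 differences passed a permutation test over peaks, with Benjamini-Hochberg adjusted p from 2e-05 to 0.00016. A wider peak meets a 1 bp overlap more easily, so the width difference can be partly built into the definition. Score and width were not separated. Neighbouring peaks are not independent, so these p-values can be too small. Scores ranked similarly in the replicates over all 384 overlapping pairs (Spearman rho 0.621, permutation p = 1e-05, the smallest possible). Over the 255 pairs that overlapped by at least 50% of each peak, rho was 0.877 (permutation p = 1e-05). These correlations are across peaks, which are not independent replicates.

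**Figure D1:**
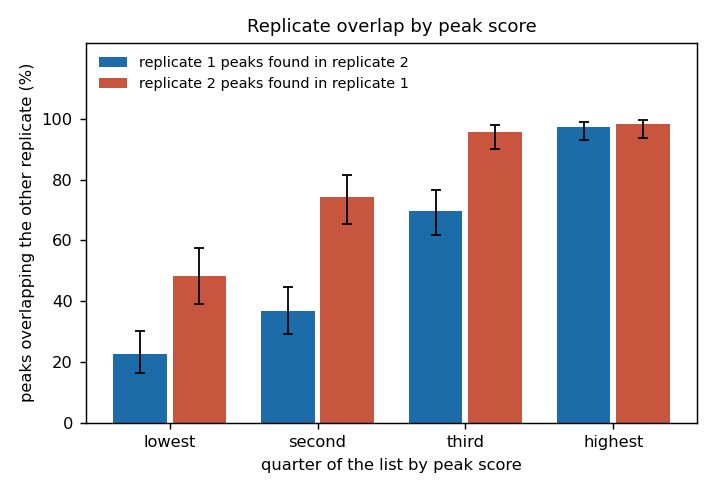
Percent of nuclear peaks (vertical axis) that overlap the other replicate by at least 1 bp, in 4 classes of the list ranked by score (horizontal axis), for replicate 1 (blue) and replicate 2 (red); bars start at 0 and whiskers are 95% Wilson intervals. The share is 22.5% and 48.2% in the lowest class and 97.2% and 98.2% in the highest.

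The series-level list was related to the replicates as follows. Of its 670 nuclear peaks, 279 (41.6%, interval 38.0 to 45.4%) overlapped both replicate lists, and these held 72.7% of its covered bases. A further 131 overlapped replicate 1 only and 41 replicate 2 only, while 219 (32.7%) overlapped neither. Peaks found in both had a median score of 16.7 and a median width of 747 bp, against 4.25 and 218 bp for those found in neither. Conversely, 92 replicate 1 peaks and 27 replicate 2 peaks had no series-level counterpart. No test was made, since the series-level list may rest on the same reads.

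The highest-scoring sites lay on all 6 nuclear chromosomes. Among the 25 series-level peaks with the highest scores that overlapped both replicates, 6 were on III, 5 on X, 4 each on I and V, 3 on IV, 2 on II and 1 on the mitochondrial genome. Their widths ran from 582 to 11168 bp with a median of 2717 bp, and their scores from 46.75 to 66.08. The highest score, 66.1, belonged to a 1054 bp peak at III 10224471 to 10225524, which scored 3123 in replicate 1 and 2887 in replicate 2. Next came an 11168 bp peak at I 15060211 to 15071378 (score 65.3), at the right end of the chromosome where the ribosomal RNA gene repeats lie. Peaks of several kilobases followed at X 289871 to 295322 (5452 bp, score 63.7), IV 11070828 to 11075796 (4969 bp, 60.2) and II 8288307 to 8292762 (4456 bp, 60.0). The next positions were held by X 15807483 to 15811181 (3699 bp, 58.7), V 5283179 to 5285895 (2717 bp, 58.1) and II 4641148 to 4645068 (3921 bp, 57.5). IV 2828427 to 2830611 (2185 bp, 55.3) and V 264953 to 267314 (2362 bp, 54.4) completed the top 10. Of the 25 peaks, 15 scored 3100 or more in replicate 1 and 13 in replicate 2. The widest series-level peak, 11706 bp at I 10207570 to 10219275, overlapped 3 peaks in replicate 1 and 8 in replicate 2. The narrowest width, 146 bp, was shared by 18 peaks, the first of them at I 1921530 to 1921675, which overlapped a peak in replicate 2 only.

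The 5 highest-scoring unshared peaks of each replicate ranked from the 73.2 to the 80.6 percentile of scores in replicate 1 and from the 51.7 to the 82.3 percentile in replicate 2. In replicate 1 the highest was I 12469161 to 12470410 (1250 bp, score 436), 375 kb from the nearest replicate 2 peak. It was followed by V 7988880 to 7991506 (score 375), X 6357657 to 6357901 (349), IV 5465181 to 5465827 (344) and IV 8578212 to 8581019 (271), which lay 63.8, 442, 166 and 109 kb from the nearest replicate 2 peak, respectively. In replicate 2 it was I 1936527 to 1937900 (1374 bp, score 798), 242 kb from the nearest replicate 1 peak. Then came III 13591274 to 13592020 (459), X 8181885 to 8182141 (208), III 13596949 to 13597269 (168) and II 1457760 to 1458012 (151). Except for the X peak, 829 kb away, these lay close to a replicate 1 peak, at 0.079, 5.75 and 0.928 kb for the peaks at III 13591274, III 13596949 and II 1457760. Of these 10 peaks, only X 6357657 to 6357901 had no counterpart in the series-level list.

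The next comparison asked whether any chromosome held more or fewer peaks than its length would give. Series-level peaks were densest on III (9.43 per Mb) and IV (8.46 per Mb) and sparsest on X (4.74 per Mb). X held 82 of 670 series-level peaks (12.2%, exact interval 9.85 to 15.0%), against 17.4% expected, 0.664 times the autosomal density (exact binomial p = 0.000345, adjusted over 3 lists 0.00103). The 6 chromosomes departed from even placement in the series-level list and in replicate 1 (chi-square statistic against multinomial draws, p = 1e-05 for each, the smallest possible) and in replicate 2 (p = 0.00542 by the same chi-square statistic). Both tests count neighbouring peaks as independent, so their p-values over single peaks can be too small. The lower density on X did not pass the test in the replicate lists, with ratios of 0.815 (exact binomial adjusted p = 0.129) and 0.899 (adjusted p = 0.454). Nor did it pass among series-level peaks overlapping both replicates (ratio 0.891), in the upper 50% by score (0.777), by covered bases (0.895), or when peaks less than 10 kb apart were joined into regions (0.919, exact binomial p = 0.692). With regions, no list departed from even placement over the 6 chromosomes (chi-square statistic, p = 0.469, 0.164 and 0.335 for the series-level list, replicate 1 and replicate 2). Median peak width was 496 bp on X against 353 bp on autosomes in the series-level list (permutation adjusted p = 0.0326). It was 328 against 303 bp in replicate 1 and 369 against 339.5 bp in replicate 2 (permutation adjusted p = 0.666 and 0.670).

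Along the chromosomes, peaks were bunched. The median gap between neighbouring peaks was 1.10 kb in the series-level list, 3.86 kb in replicate 1 and 3.74 kb in replicate 2. Random placement gave 98.6, 116 and 150 kb, respectively (placement permutation test, two-sided p = 0.0002 for each, the smallest possible). Gaps under 1 kb made up 48.3% of series-level gaps. The gap was far longer, though still under chance, in subsets of the series-level list. These hold fewer peaks, so the gap given by random placement was longer as well. It was 127756 bp for series-level peaks overlapping both replicates (chance 239832 bp) and 74846 bp for the upper 50% by score (chance 199822 bp). Joined within 10 kb, the 670 nuclear series-level peaks formed 278 regions, of which 179 held a single peak and 26 held 5 or more peaks, 303 peaks in all. The median gap between these regions was 240336 bp, against 241108 bp for regions placed at random (placement permutation p = 0.968). Joined regions lie at least 10 kb apart by construction, while regions placed at random can lie closer or overlap. The comparison therefore leans towards finding no bunching of regions.

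Single peaks lay in the outer parts of chromosomes more often than under independent random placement in replicate 2, while the full series-level list and replicate 1 did not pass the test. The outer parts held 67.3% of series-level peaks, against 66.6% for random placement (placement permutation p = 0.745, adjusted over 3 lists 0.745). Replicate 1 had 65.8% there (permutation adjusted p = 0.745) and replicate 2 had 75.6% (permutation adjusted p = 0.0006). The placement moves each peak independently although peaks were bunched, so the p-values over single peaks in this paragraph can be too small. Rotation of the list, which keeps the bunching, was run for the series-level list only (rotation permutation p = 0.897). On chromosome I the left, central and right parts held 38, 9 and 47 series-level peaks, while on IV they held 12, 90 and 46. Of the 90, 57 lay in 1 dense region of 61.8 kb, IV 6668654 to 6730413. Without that region the outer share was 73.6% in the series-level list (placement permutation p = 0.0004) and 71.9% in replicate 1 (p = 0.011), and both passed the test. Leaving out the dense region III 7405449 to 7451769 instead, also in a central part, gave 72.2% in the series-level list (placement permutation p = 0.0028) and 68.9% in replicate 1 (p = 0.287). Leaving out any other of the 10 densest regions gave no call in either list, and replicate 2 passed the test without any 1 of the 10. Both named regions were left out after seeing the data, and removing peaks from a central part can only raise the outer share. Joined regions, a unit added after seeing the data, lay in the outer parts more often than by chance. Their share was 77.7% of 278 regions in the series-level list (permutation adjusted p = 0.0006), 74.7% of 273 in replicate 1 (adjusted p = 0.0042) and 76.4% of 212 in replicate 2 (adjusted p = 0.0039). The outer share also passed the test among series-level peaks overlapping both replicates (74.9%, placement permutation p = 0.003) and in the upper 50% by score (72.8%, p = 0.0154).

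**Figure D2:**
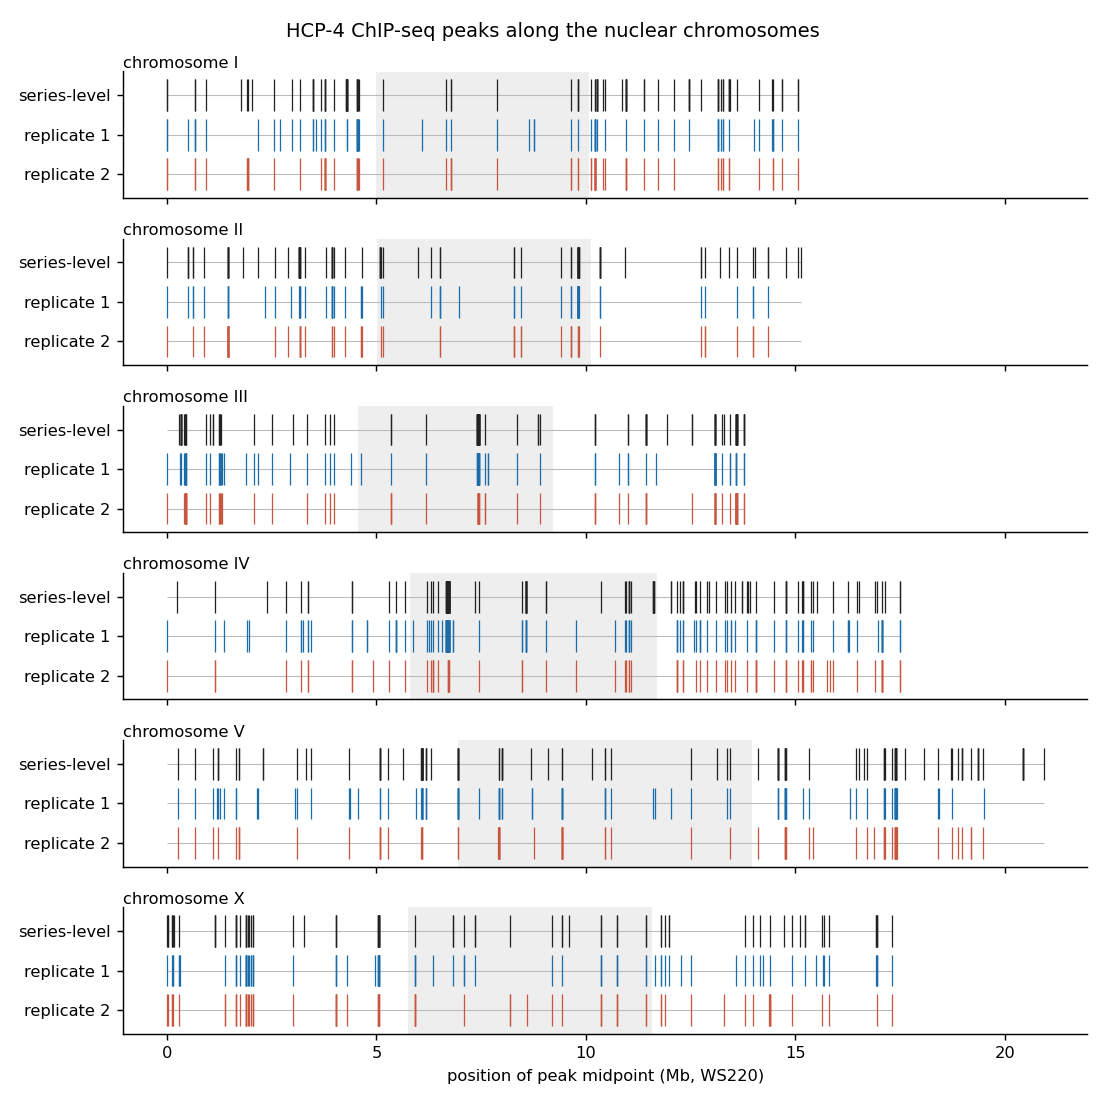
Midpoints of peaks (vertical ticks) along each nuclear chromosome in Mb on WS220 for the series-level list (black), replicate 1 (blue) and replicate 2 (red); grey marks the central part of 3. Peaks are bunched, with 278 regions among 670 series-level peaks, and 77.7% of regions but 67.3% of single peaks lie outside the grey part.

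Some dense regions were not equally represented in the replicates. The densest, IV 6668654 to 6730413, held 57 series-level peaks within 61.8 kb, with 48 peaks in replicate 1 and 5 in replicate 2. This was 8.45% of replicate 1 peaks and 1.12% of replicate 2 peaks (Fisher's exact p = 3.69e-08, adjusted over the 10 densest regions 3.69e-07). The second, III 7405449 to 7451769, held 45 series-level peaks, with 25 and 13 in replicates 1 and 2 (Fisher's exact adjusted p = 0.479). II 9807974 to 9825169 held 19 and 3 (Fisher's exact adjusted p = 0.0127), and III 13584217 to 13599001 held 4 and 21 (adjusted p = 0.000238). The other 6 of the 10 densest regions did not pass the test. Chromosome IV as a whole held 25.4% of replicate 1 and 17.2% of replicate 2 peaks (Fisher's exact p = 0.00214, adjusted over 6 chromosomes 0.0128). Outside the densest region the shares were 18.5% and 16.3% (Fisher's exact p = 0.395), and counted as joined regions IV held 22.7% and 22.6% (Fisher's exact p = 1). Neighbouring peaks in a region are not independent, so these p-values are too small.

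**Figure D3:**
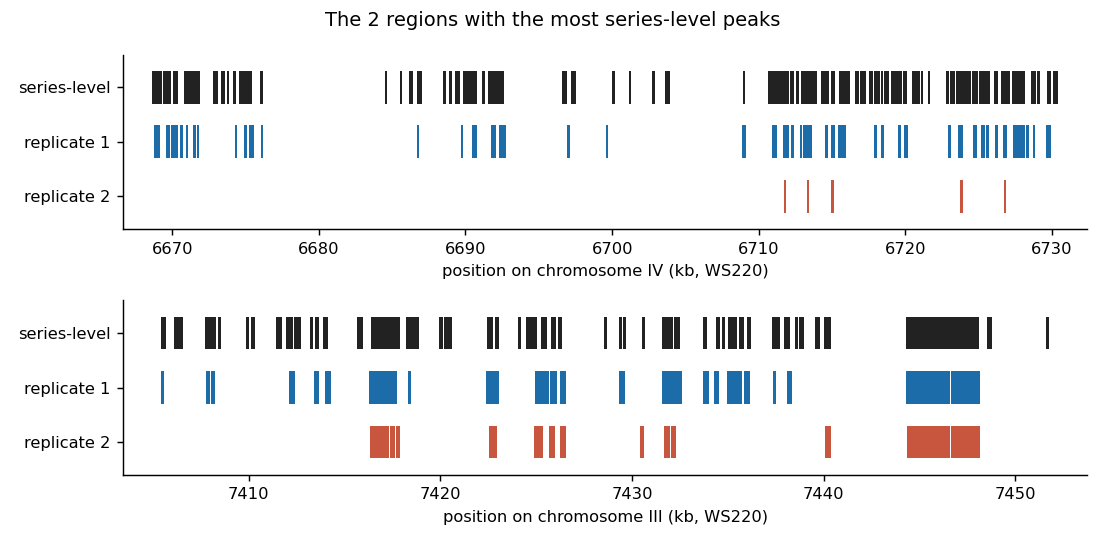
Peaks as boxes to scale along 2 regions, in kb on WS220, for the series-level list (black), replicate 1 (blue) and replicate 2 (red). In the chromosome IV region there are 57, 48 and 5 peaks, and in the chromosome III region 45, 25 and 13.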

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

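The tests on the mitochondrial genome and on the chromosome IV region were all chosen after the imbalance or signal they address had been seen.

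Peaks were called over most of the mitochondrial genome, which lies outside the nuclear comparisons. They covered 13116 bp in the series-level list (2 peaks, scores 50.3 and 42.7), 13401 bp in replicate 1 (1 peak, score 3100) and 13285 bp in replicate 2 (1 peak, score 848). The smallest of these is 95.1% of the nominal mitochondrial length. A candidate explanation is multi-copy DNA represented unequally in ChIP and input, which would also give signal at the ribosomal repeats at the right end of chromosome I, where 3 of 3 lists have a peak over 10 kb wide. This stays open, since HCP-4 could also bind that end and input coverage was not analysed here; binding of HCP-4 to mitochondrial DNA was not tested.

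In the densest region, IV 6668654 to 6730413, 48 peaks were called in replicate 1 and 5 in replicate 2. Lower sensitivity of replicate 2 for weak peaks everywhere stays open: 10.4% of the replicate 1 peaks inside (5 of 48) overlapped replicate 2, against a mean of 40.3% in score-matched draws from the other replicate 1 peaks, but neighbouring peaks are not independent. Over the 18 replicate 1 regions of 5 or more peaks, the share minus its score-matched share ran from -56 to 32.5 percentage points. The 2 regions in this stretch are among the 18, with 12 and 37 peaks, and were at -42.9 and -25.5. The first of them starts at IV 6668341, left of the stretch, so its peaks include a peak outside it. The value of -56 came from a region of 5 peaks. Of the 18 regions, 2 fell at least as low as -42.9, a share of 0.111, and more fell at least as low as -25.5. A share under 0.05 was required, but the smallest possible with 18 regions is 0.0556, so this comparison could not decide. A difference in the DNA or background of this stretch between the preparations also stays open: the median score of its replicate 1 peaks was 72.6 against 115 elsewhere (permutation p = 0.0807), and no read coverage was analysed here. Both libraries carry the same group label, so no biological explanation was tested.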

How the results depend on the processing

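Joining peaks within 10 kb, gaps over 10 kb, nominal lengths, rotation for the outer parts and leaving out dense regions were chosen after seeing the data. Of 42 alternatives, 38 had a test: 25 left the call or its absence unchanged, including all 12 for replicate overlap and both for the correlation of scores, 7 lost a call, 5 gained one and 1 reversed the direction with a call. The other 4, without a test, moved. The low density on X (ratio 0.664) lost its call in the single replicate lists (0.815 to 0.899), among peaks overlapping both replicates (0.891), in the upper 50% by score (0.777), by bases (0.895) and after joining (0.919). Without the densest IV region it was 0.735 and kept its call (exact binomial p = 0.00888). The outer share (67.3%, no call) passed the threshold among peaks overlapping both replicates (74.9%), in the upper 50% by score (72.8%), after joining (77.7%) and without the densest IV region (73.6%), whose removal can only raise it since the region is central. In single replicate lists it ran from 65.8 to 75.6%, with a call in replicate 2 only; the lower value, and 46.9% with narrower outer parts, lay below chance without a call. The median gap of 1102 bp became 3737 to 3855 bp in single replicate lists. With gaps over 10 kb only it was 240336 bp and above chance (109670 bp), a reversal by construction since close gaps were removed. Joined regions placed at random gave 241108 bp and ended the call (permutation p = 0.968), but placed regions can lie closer than the 10 kb that joining enforces. Median width rose from 362 to 723.5 and 1067.5 bp in the upper 50% and 25% by score. The share of series-level peaks in both replicates moved from 41.6 to 25.2% with overlap of 50% of each peak and to 51.3% in the upper 50% of each list. Apart from the reversal, the cause of these changes was not tested. No paired analysis was possible because the input libraries that share replicate numbers with the ChIP libraries were not analysed here. Read depth is unknown, so whether it limits the overlap of weak peaks cannot be settled. The 4 planned results that need WS220 annotation or sequence were not run.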

Other observations

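Joining peaks into regions was chosen after seeing the data, and the test of close gaps before its value was seen.

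Some chromosome ends carried peaks. On the left, a peak began within the first 10 bases of 5 of 6 nuclear chromosomes in each replicate (I, II, III, IV and X) and of 3 in the series-level list (I, II and X). Chromosome V had no peak at its left end, its first peak starting at 264953 in the series-level list. On the right, the last series-level peaks of I, III, IV and V ended 16, 31, 31 and 32 bp beyond the nominal chromosome length, while those of II and X ended more than 2 kb short of it. In both replicates the last peaks of I, III and IV ended within 2 kb of the nominal end without passing it, and those of II, V and X ended more than 2 kb short.

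Part of the unshared peaks lay within 10 kb of a peak called in the other replicate. The share expected by chance was not computed for this distance, and unshared peaks can be bunched in dense regions. Of 247 replicate 1 peaks with no overlap in replicate 2, 122 (49.4%) were within 10 kb of a replicate 2 peak. Of 94 unshared replicate 2 peaks, 64 (68.1%) were within 10 kb of a replicate 1 peak. As joined regions, 187 of 212 in replicate 2 (88.2%) and 185 of 273 in replicate 1 (67.8%) overlapped the other replicate.

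Neighbouring peaks less than 1 kb apart made up 48.3% of series-level gaps, and such gaps could arise where a peak caller splits continuous broad enrichment. Where both flanking peaks were also called in a replicate, a single replicate peak bridged the gap in 34.7% of 225 cases (95% Wilson interval 28.8 to 41.1%), 54 of 140 in replicate 1 and 24 of 85 in replicate 2. The 225 cases pool the replicates, so the same gap can count in each. The interval treats them as independent and can be too narrow. A share under 50% had been set beforehand as evidence against splitting, and that bound was judged wrong only after the value was seen. Versions of the same caller made all 3 lists and can split a stretch at the same place, so a low share does not exclude splitting. The explanation stays open.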
